A study of Homo sapiens with 36 samples.

How the data were processed

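The series covers HCT116 cells treated with 10 µM 5-FU for 48 h and sampled on 6 days, with cytoplasmic RNA and a heavy polysomal pool from each collection, 3 replicate letters per group and 36 libraries in 12 groups. Per the labels' protocols, cells were treated with emetine, nuclei and mitochondria were pelleted, and the remaining lysate was run on a sucrose gradient from which fractions with more than 3 ribosomes per mRNA were pooled. Libraries were poly(A)-selected and made with a dUTP strand-marking kit, per the labels' protocols. Per the submitters' processing notes, the authors used FastQC 0.11.9, cutadapt 3.2, STAR 2.7.9a on GRCh38, featureCounts of Subread 2.0.1 and DESeq2 1.30.1. The strand setting of the counting was not given in the sources used here, and neither was what was done to the cells between D14 and D16. The deposited values are a signal, gene read counts divided by 1 size factor per library (normalised counts), as the authors' table gives them.

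The table has 54 columns, of which 36 belong to the samples, and 18 belong to none and were not used here. It lists 15891 genes, all with a value over 1 in every column (the smallest was 1.004). Genes silent in any library are thus absent and could not be analysed here. DPYD was not listed either, for a reason that is not stated. Each deposited value was divided by the value of 1 read of its library. This gave whole reads for 100 percent of values within 0.01, and the depth of each library was summed from these reads. Symbols were matched for 15856 gene identifiers, and 15799 were found in GENCODE 29, whose GRCh38 coordinates and exon lengths were used, with 12399 protein-coding genes. The other identifiers were tested without a symbol or length.

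Values were transformed to log2(value + 1). Genes with at least 10 in at least 3 libraries of the fraction were kept. limma 3.58.1 (lmFit, then eBayes with trend, R 4.3.3) was fitted to the group means of all days within a fraction, and to all 12 groups for polysome association, the difference of heavy and cytoplasmic changes. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. F tests asked for a change on any day. Each comparison with D0 uses the same D0 libraries, so their lists were not overlapped or correlated with each other. Correlations between fractions were computed within each letter.

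A set of 31 gene lists was written from general knowledge before the data were examined, as were the comparisons, tests, filter, thresholds and most alternatives. The lists cover p53 targets, DNA replication, mitosis, fluoropyrimidine metabolism, cytosolic ribosomal proteins, TOP translation factors, ribosome biogenesis, aminoacyl-tRNA synthetases, ATF4 targets, unfolded protein response, interferon-stimulated genes, antigen presentation, NF-κB and secretory genes, cholesterol, glycolysis and hypoxia, OXPHOS, mitochondrially encoded genes, lysosome and autophagy, DNA repair, apoptosis, Wnt and stem cell genes, intestinal differentiation, epithelial junction, mesenchymal genes, YAP targets, other cell lineages, nuclear-retained RNAs, histones, senescence and lamins, initiation and mTOR, and drug efflux. Lists were tested with camera at its preset correlation of 0.01, which compares a list with the other genes, with camera at an estimated correlation, and with fry, which tests whether the genes of a set move on balance in a single direction and does not compare them with other genes. Genes are named by a rule fixed beforehand. It takes, in each comparison, the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 100 in a compared group and the same sign in all 3 letters, up to 4 called members of each list, and a fixed set that includes CDKN1A, MDM2, TYMS, RRM2 and MYC. Some genes that the rule takes are not reported here.

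The letters pair samples, since the labels give each letter as a batch. The pairing was checked by correlating deviations of libraries from group means. Same-letter pairs had a mean r of 0.24 between days in the cytoplasm (28 of 45 pairs over 0.1), 0.11 in the heavy pool (25 of 45) and -0.02 between the cytoplasm and the heavy pool of a day (5 of 18). Different-letter means (-0.11, -0.05 and 0.01) largely follow from the centring and are no baseline. The highest cytoplasmic same-letter r was 0.93. The main fit had no letter block, so its p-values leave this pairing out. An alternative had one.

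The steps were tested on simulated data with 50 changed genes per fold size. At 1.5-, 2-, 4- and 8-fold, 0, 14, 39 and 46 genes were recovered for the cytoplasm at D2 (6 false calls among 15889 genes), 32, 45, 47 and 50 for the heavy pool (16 false calls among 15852) and 5, 9, 35 and 49 for polysome association (6 false calls among 15891). A raised set of 100 genes was called in all 3 cases, and 0 of 30 random sets were. The genes were simulated independently, without correlation between genes or trends shared within a library or letter. These counts therefore do not give the rate of false calls in the real data, least of all for gene lists.

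Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM and total-sum scaling, the replicate block, leaving out each letter and each library, a fit of only the groups compared, 1 ratio per culture, Spearman correlation, and tests of the recovered reads by edgeR 4.0.16 and DESeq2 1.42.0, which stood for the authors' count model. Added after the data were seen were a fit without cytoplasmic libraries D7 A, D14 B and D16 B, removal of each library's trend with exon length and GC content, with and without the block, and correlations without each letter. Libraries were also regrouped, in all 10 splits for each pair of groups and in 100 groupings for the F tests, the real one and random ones. Data were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.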

Results

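HCT116 is a cell line from a human colorectal carcinoma, and 5-fluorouracil (5-FU) is a pyrimidine analogue that blocks the synthesis of thymidylate and is built into RNA and DNA. Per the labels, the cells received 10 µM 5-FU for 48 h. They were collected before the drug (D0) and on D1, D2, D7, D14 and D16. D1 and D2 lay within these 48 h and the later days after them. What was done to the cells between D14 and D16 was not given. The samples hold no untreated culture from the later days, so effects of the drug and of time in culture cannot be told apart. Each collection gave cytoplasmic RNA and a heavy polysomal pool, the part of a sucrose gradient that holds mRNA bound by more than 3 ribosomes and thus engaged in translation. The table held 12 groups of 3 libraries (letters A, B and C), 36 libraries in all, and 15891 genes. Read totals over these genes, in megareads, ran from 41.0 to 103.6 in the cytoplasmic libraries (median 48.05) and from 46.1 to 55.7 in the heavy pool (median 51.7). The highest cytoplasmic total belonged to D2 C, and the next was 55.2. The labels do not say whether the letters were separate cultures, so the p-values below measure the spread between these samples.

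Differences are given as log2(value + 1) ± standard error from limma, from 3 libraries per group (n = 3), and p-values are limma's, adjusted for all genes tested. The added 1 makes the fold change of weakly expressed genes look smaller than it was. For gene lists, "over the list alone" gives the numbers that rose and fell when p-values were corrected within the list only. The strand setting was not stated, so a change in a gene overlapping another on the opposite strand may be its neighbour's. Values of the KRTAP2 family, LGALS7B, RGPD1 and RGPD2 are uncertain, since these genes have near-identical copies.

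Libraries of the same group spread more in the cytoplasm than in the heavy pool. The standard deviation of a library around its group mean was 0.16 to 0.552 on the log2 scale in the cytoplasm and 0.108 to 0.208 in the heavy pool, which let more genes pass in the heavy pool at the same size of change. Transcripts of the mitochondrial chromosome made up 3.57 to 13.57 percent of cytoplasmic reads and 0.18 to 3.93 percent of heavy pool reads. Cytoplasmic library D7 A stood apart with 22.7 percent of its reads in ribosomal protein genes. Libraries D14 B and D16 B deviated from their groups along the GC content of the genes (r across genes 0.81 and 0.76). Some other libraries deviated along GC content too, for example cytoplasmic D1 B (0.59). A change between days was found for 9769 genes in the cytoplasm, 15078 in the heavy pool and 8602 in the ratio of the heavy pool to the cytoplasm (limma F tests).

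Before the drug, mRNAs of the replication machinery were enriched in the heavy pool. Ribosomal protein mRNAs, mitochondrial transcripts and RNAs listed as nuclear-retained were depleted relative to the cytoplasm. The helicase subunit MCM6 (1.34 ± 0.16, adjusted p = 2.88e-07) and the mitotic cyclin CCNB1 (1.05 ± 0.11) were enriched in the heavy pool, together with SRCAP (1.77 ± 0.48), a chromatin remodeller, and EDC4 (1.62 ± 0.45), a decapping scaffold. Strongly depleted were FTL (-2.56 ± 0.18, adjusted p = 6.35e-11), the iron-storage light chain, whose translation is held back by an RNA element, PPDPF (-2.73 ± 0.22), SVIP (-2.48 ± 0.35) and POPDC3 (-2.74 ± 0.35). Enrichment or depletion was called for 7280 of 15891 genes (4249 higher and 3031 lower in the heavy pool), with a median over all genes of 0.14.

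Among cytosolic ribosomal protein mRNAs, which carry a terminal oligopyrimidine start that ties their translation to mTOR, 0 of 77 were enriched, 64 were depleted and 13 did not pass (0 and 68 over the list alone, median -1.04, camera adjusted p = 7.73e-19, or 0.399 with an estimated correlation), with RPL12 (-2.21 ± 0.29), RPS12 (-2.12 ± 0.33) and RPL17 (-1.85 ± 0.15) the lowest. The translation elongation factor EEF1A1 (-0.50 ± 0.14) and the stalk protein RPLP0 (-1.19 ± 0.16) were depleted as well. For mitochondrially encoded mRNAs, which are translated inside the organelle, 0 of 13 were enriched, 10 were depleted and 3 did not pass (0 and 10 over the list alone, median -1.50, camera adjusted p = 2.43e-05, or 0.402 with an estimated correlation). The nuclear noncoding RNAs MALAT1 (-2.12 ± 0.45) and PVT1 (-2.14 ± 0.22) headed a list in which 0 of 9 were enriched, 7 were depleted and 2 did not pass (0 and 7 over the list alone, median -1.31, camera adjusted p = 9.03e-05, or 0.213 with an estimated correlation). On the other side stood DNA replication genes, of which 27 of 35 were enriched, 2 were depleted and 6 did not pass (28 and 2 over the list alone, median 0.77, camera adjusted p = 1.93e-07, or 0.213 with an estimated correlation). Aminoacyl-tRNA synthetases, of which 17 of 20 were enriched, 0 were depleted and 3 did not pass (17 and 0 over the list alone, median 0.78, camera adjusted p = 2.17e-06, or 0.165 with an estimated correlation), included MARS1 (1.12 ± 0.16). For glycolysis genes 19 of 27 were enriched, 2 were depleted and 6 did not pass (19 and 2 over the list alone, median 0.72, camera adjusted p = 0.00527, or 0.553 with an estimated correlation). None of the camera calls at baseline held with an estimated correlation.

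At D1 the cytoplasm showed a p53 response. The cell cycle inhibitor CDKN1A (3.60 ± 0.23, adjusted p = 1.03e-08), the stress cytokine GDF15 (3.94 ± 0.18, adjusted p = 3.05e-10) and the oxidoreductase TP53I3 (4.10 ± 0.20, adjusted p = 6.88e-10) rose, and so did the ubiquitin ligase MDM2 (1.60 ± 0.31, adjusted p = 0.00198). CDKN1A (chromosome 6, 36676460 to 36687339) went from 7110 ± 584 to 86800 ± 11900 (mean ± SD, n = 3), and MDM2 (chromosome 12, 68808176 to 68850686) from 2780 ± 423 to 8380 ± 1060. Among p53 targets, 27 of 30 rose, 0 fell and 3 did not pass (28 and 0 over the list alone, median 1.79, camera adjusted p = 1.7e-27), including the kinase PLK3 (3.07 ± 0.25).

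Among the largest rises were those of HMCN2 (6.55 ± 0.37, adjusted p = 2.95e-09), a matrix protein, NECTIN4 (5.56 ± 0.21, adjusted p = 2.29e-11), an adhesion receptor, PTAFR (5.49 ± 0.34), the receptor for platelet-activating factor, ITGAM (4.99 ± 0.55), an integrin of myeloid cells, and KLHDC7A (4.92 ± 0.67). Of the apoptosis regulators 10 of 26 rose, 0 fell and 16 did not pass (11 and 1 over the list alone, median 0.46, camera adjusted p = 0.00262), led by the BH3-only gene BBC3 (2.31 ± 0.22), BAX (1.97 ± 0.22) and the death receptor FAS (1.88 ± 0.43). NF-κB and secretory genes took part, where 10 of 20 rose, 0 fell and 10 did not pass (11 and 1 over the list alone, median 1.12, camera adjusted p = 8.82e-06). Among them were IL11 (2.65 ± 0.42) and ICAM1 (2.13 ± 0.30). Of the interferon-stimulated genes 7 of 26 rose, 0 fell and 19 did not pass (7 and 0 over the list alone, median 0.38, camera adjusted p = 0.0122). This list call was lost without letter A (adjusted p = 0.112). The genes OASL (2.85 ± 0.25) and ISG15 (2.51 ± 0.34) rose.

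Falls at D1 included those of SLC7A11 (-2.33 ± 0.32, adjusted p = 9.18e-05), the cystine importer, and RPL22L1 (-2.20 ± 0.37). Mitotic mRNAs had begun to drop, as 0 of 35 rose, 11 fell and 24 did not pass (0 and 14 over the list alone, median -0.71, camera adjusted p = 2e-06, or 0.0636 with an estimated correlation), with PLK1 (-1.31 ± 0.20). For DNA replication genes 4 of 35 rose, 2 fell and 29 did not pass (4 and 3 over the list alone, median -0.11, camera adjusted p = 0.682), with MCM6 (-1.37 ± 0.21) and PCNA (0.88 ± 0.19) moving apart. The drug's target, thymidylate synthase, did not pass, TYMS (0.04 ± 0.19, adjusted p = 0.909). Aminoacyl-tRNA synthetases, which charge tRNAs, declined, as 1 of 20 rose, 6 fell and 13 did not pass (2 and 10 over the list alone, median -0.57, camera adjusted p = 0.000936), for example MARS1 (-1.18 ± 0.17). Of the ribosome biogenesis genes 1 of 40 rose, 7 fell and 32 did not pass (1 and 7 over the list alone, median -0.35, camera adjusted p = 0.00905). In all, 2850 of 15889 genes changed, 1724 higher and 1126 lower, a share of 60.5 percent higher that became 46.1 percent under total-sum scaling, with 1733 changed at least 2-fold.

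At D2, the end of the exposure, p53 targets were high and mitotic and replication mRNAs low. CDKN1A (4.51 ± 0.23, adjusted p = 3.23e-10) reached its highest mean and PLK1 (-3.05 ± 0.20, adjusted p = 8.29e-09), a kinase that drives entry into mitosis, its lowest, from 15100 ± 1720 to 1830 ± 334 (chromosome 16, 23677656 to 23690367). Of the mitotic genes 0 of 35 rose, 31 fell and 4 did not pass (0 and 33 over the list alone, median -1.62, camera adjusted p = 3.19e-20). Among them were HMMR (-3.80 ± 0.67), ASPM (-2.58 ± 0.50), TTK (-2.20 ± 0.59) and CCNB1 (-2.13 ± 0.15). Of the DNA replication genes 0 of 35 rose, 26 fell and 9 did not pass (1 and 28 over the list alone, median -1.17, camera adjusted p = 2.76e-15). Among them were POLA1 (-2.68 ± 0.30), MCM2 (-2.23 ± 0.28) and MCM3 (-2.08 ± 0.16). The nuclear lamin LMNB1 (-2.60 ± 0.23) fell too.

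Among p53 targets 28 of 30 rose, 0 fell and 2 did not pass (28 and 0 over the list alone, median 2.16, camera adjusted p = 3.85e-25). Among them were TP53I3 (4.40 ± 0.20), GDF15 (3.99 ± 0.18), TP53INP1 (3.89 ± 0.23) and MDM2 (1.95 ± 0.31). Among apoptosis regulators 12 of 26 rose, 1 fell and 13 did not pass (12 and 1 over the list alone, median 0.60, camera adjusted p = 0.000108). Among them were FAS (2.40 ± 0.43) and BIRC3 (2.87 ± 0.59). Large rises included those of PTAFR (6.70 ± 0.34) and ELAPOR1 (4.94 ± 0.30). The NF-κB and secretory list was up, as 13 of 20 rose, 1 fell and 6 did not pass (14 and 1 over the list alone, median 1.52, camera adjusted p = 7.04e-08). The interferon-stimulated list was up too, where 11 of 26 rose, 0 fell and 15 did not pass (11 and 0 over the list alone, median 0.85, camera adjusted p = 7.24e-05). Among them were OASL (4.22 ± 0.25) and ISG15 (3.84 ± 0.34, adjusted p = 2.53e-07). For the antigen presentation genes 8 of 14 rose, 0 fell and 6 did not pass (9 and 0 over the list alone, median 0.81, camera adjusted p = 6.23e-05, or 0.0805 with an estimated correlation). Among them was the peptide transporter TAP1 (2.05 ± 0.24).

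At D2 TYMS (-1.14 ± 0.19, adjusted p = 0.000215) fell, from 20000 ± 540 to 9330 ± 2760 (chromosome 18, 657604 to 673578), as did DUT (-2.03 ± 0.22), which removes dUTP, and the folate enzyme SHMT2 (-1.15 ± 0.26), whereas RRM2 (-0.22 ± 0.16, adjusted p = 0.35) did not pass. Within the fluoropyrimidine list 2 of 27 rose, 8 fell and 17 did not pass (2 and 10 over the list alone, median -0.27, camera adjusted p = 0.0139, or 0.142 with an estimated correlation). That call was also lost without letter C (adjusted p = 0.069). Of the aminoacyl-tRNA synthetases 0 of 20 rose, 13 fell and 7 did not pass (0 and 14 over the list alone, median -1.07, camera adjusted p = 6.43e-09). Of the ribosome biogenesis genes 0 of 40 rose, 14 fell and 26 did not pass (0 and 18 over the list alone, median -0.56, camera adjusted p = 3.8e-08). Among them were UTP20 (-2.27 ± 0.23) and the nucleolar protein NCL (-1.76 ± 0.27). Of the ATF4 targets 4 of 26 rose, 14 fell and 8 did not pass (5 and 15 over the list alone, median -0.89, camera adjusted p = 0.00124, or 0.142 with an estimated correlation), with the serine synthesis enzymes PHGDH (-2.27 ± 0.22) and PSAT1 (-2.10 ± 0.17) falling and ATF3 (2.32 ± 0.18) rising. Among DNA repair genes 0 of 31 rose, 14 fell and 17 did not pass (0 and 15 over the list alone, median -0.93, camera adjusted p = 1.83e-06, or 0.0805 with an estimated correlation). Among them were MSH6 (-2.35 ± 0.28) and XRCC2 (-1.89 ± 0.36). The day changed 3943 genes, 2255 higher and 1688 lower.

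Other lists at D2 moved less evenly. Of the lysosome and autophagy genes 9 of 30 rose, 0 fell and 21 did not pass (10 and 0 over the list alone, median 0.38, camera adjusted p = 0.00224, or 0.243 with an estimated correlation). Among them was the sialidase NEU1 (1.67 ± 0.20). Of the mesenchymal genes 7 of 20 rose, 1 fell and 12 did not pass (8 and 2 over the list alone, median 0.76, camera adjusted p = 0.0134, or 0.255 with an estimated correlation), with SNAI2 (3.22 ± 0.75), ACTA2 (3.21 ± 0.27) and VIM (-2.49 ± 0.34) moving apart. Of the senescence and lamin genes 3 of 19 rose, 8 fell and 8 did not pass (3 and 10 over the list alone, median -0.49, camera adjusted p = 0.0104, or 0.151 with an estimated correlation), with the inhibitor CDKN2B (2.19 ± 0.22) rising and HMGB2 (-2.23 ± 0.28) falling. Drug efflux and detoxification genes split, as 5 of 21 rose, 3 fell and 13 did not pass (5 and 3 over the list alone, median 0.34, camera adjusted p = 0.519), with the pump ABCG2 (1.57 ± 0.41) rising. The list of initiation and mTOR genes split too, as 3 of 28 rose, 2 fell and 23 did not pass (3 and 2 over the list alone, median -0.10, camera adjusted p = 0.564). In the Wnt and stem cell list 2 of 17 rose, 2 fell and 13 did not pass (2 and 2 over the list alone, median -0.25, camera adjusted p = 0.361). Among them was AXIN2 (-2.01 ± 0.29). Only 5 of 32 intestinal differentiation genes were listed in the table, and 1 of 5 rose, 0 fell and 4 did not pass (1 and 0 over the list alone, median 0.60, camera adjusted p = 0.108). Of the 22 markers of other cell lineages 3 were listed (ITGAM, HBA1 and COL1A1), and 2 of 3 rose, 0 fell and 1 did not pass (3 and 0 over the list alone, median 1.48, camera adjusted p = 0.0117, or 0.0554 with an estimated correlation).

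**Figure D1:**
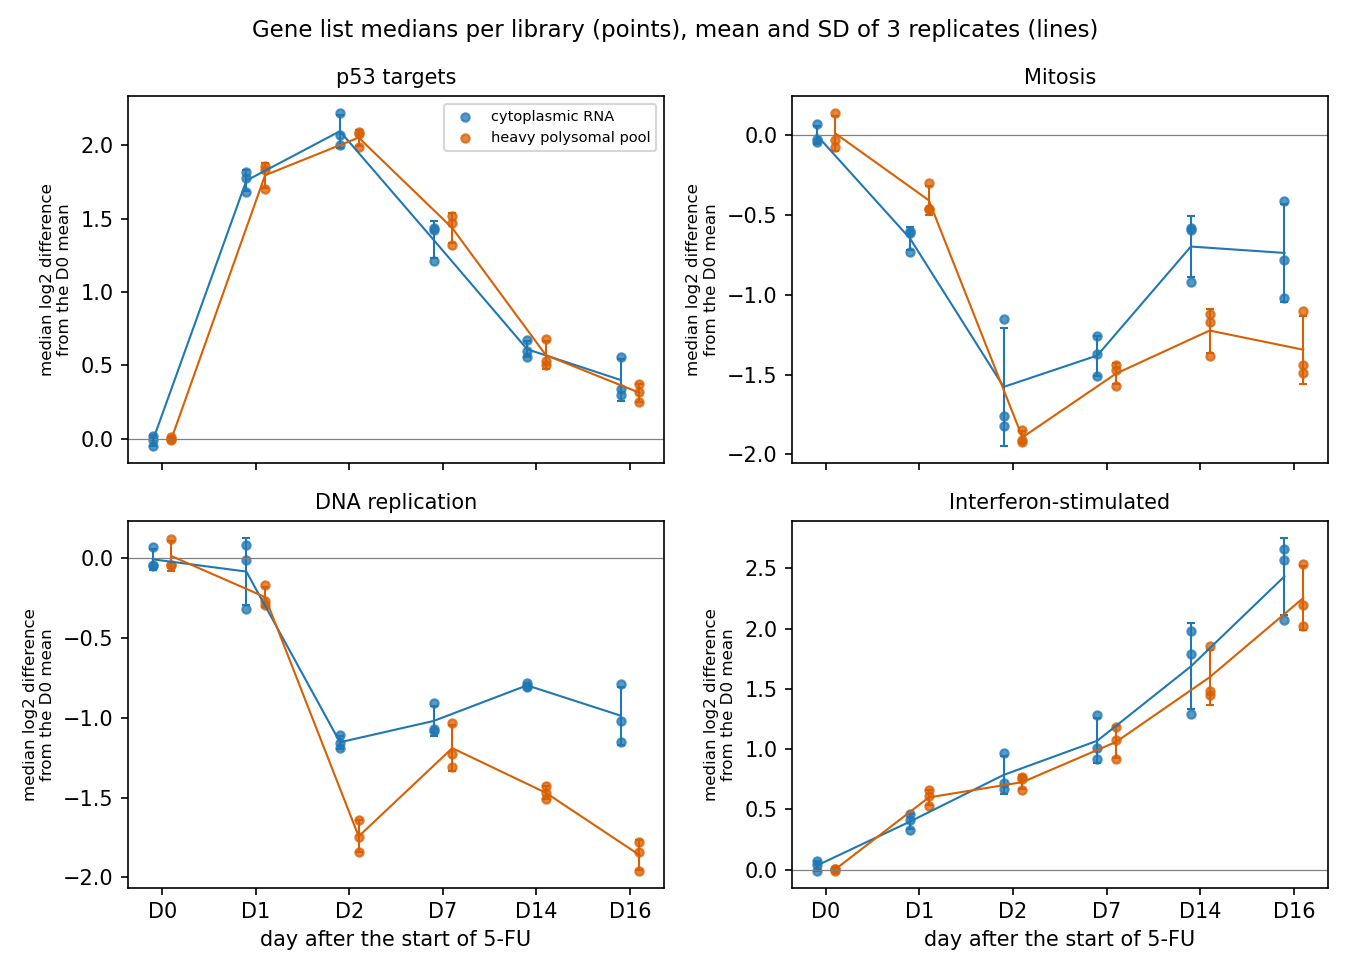
Median over the members of 4 gene lists of the log2 difference of each library from the D0 mean of its fraction, by day (days spaced evenly), in cytoplasmic RNA and the heavy polysomal pool, with points for libraries and lines for the mean and SD of 3 replicates. The p53 targets have their highest mean at D2 (CDKN1A among them), mitosis and DNA replication genes are lowest in the cytoplasm at D2, and interferon-stimulated genes climb to D16.

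At D7, days after the drug, replication and mitosis mRNAs were still low. KRTAP3-1 (8.66 ± 0.44, adjusted p = 3.68e-10), a hair keratin partner, and KLK5 (5.86 ± 0.26, adjusted p = 7.91e-11), a protease of the skin barrier, rose most, followed by KRTAP2-3 (5.79 ± 0.21) of a family with near-identical copies, NRG1 (5.71 ± 0.33, adjusted p = 3.14e-09), a ligand of ERBB receptors, and PRR15L (4.94 ± 0.55). CDKN1A (3.18 ± 0.23, adjusted p = 4.28e-08) was still high, and of the p53 targets 21 of 30 rose, 0 fell and 9 did not pass (26 and 0 over the list alone, median 1.34, camera adjusted p = 3.84e-14). Among mitotic genes 0 of 35 rose, 25 fell and 10 did not pass (0 and 27 over the list alone, median -1.38, camera adjusted p = 3.2e-13). Among them were PRC1 (-3.33 ± 0.65), ESPL1 (-2.42 ± 0.35) and BUB1B (-2.20 ± 0.31). Among DNA replication genes 0 of 35 rose, 25 fell and 10 did not pass (0 and 28 over the list alone, median -1.11, camera adjusted p = 1.11e-12). Among them were MCM2 (-1.89 ± 0.28), UHRF1 (-1.82 ± 0.20) and POLE (-1.71 ± 0.33). TYMS (-0.34 ± 0.19, adjusted p = 0.164) did not pass.

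Ribosomal protein mRNAs rose as a body at D7, as 53 of 77 rose, 0 fell and 24 did not pass (69 and 0 over the list alone, median 1.06, camera adjusted p = 2.7e-12, or 0.428 with an estimated correlation), with RPL26 (1.61 ± 0.43) and RPS12 (1.55 ± 0.44). OXPHOS subunits rose too, as 24 of 51 rose, 3 fell and 24 did not pass (28 and 4 over the list alone, median 0.89, camera adjusted p = 0.000471, or 0.572 with an estimated correlation). Among them were COX6A1 (2.07 ± 0.47) and NDUFC2 (1.86 ± 0.42). Library D7 A held 22.7 percent of its reads in ribosomal protein genes, as given above. Replication-dependent histone mRNAs, found in poly(A) libraries only when polyadenylated, also rose, as 8 of 11 rose, 1 fell and 2 did not pass (9 and 1 over the list alone, median 2.16, camera adjusted p = 3.52e-06, or 0.1 with an estimated correlation). Among them was H2BC5 (4.44 ± 0.32, adjusted p = 4.2e-08). Interferon-stimulated genes were higher, as 15 of 26 rose, 2 fell and 9 did not pass (16 and 2 over the list alone, median 0.94, camera adjusted p = 2.58e-05). Among them were IFIT3 (3.27 ± 0.45), IFI27 (3.09 ± 0.42) and IFI6 (2.88 ± 0.31). The chemokines CXCL1 (2.68 ± 0.41) and CXCL8 (2.58 ± 0.59) rose within a list of which 11 of 20 rose, 1 fell and 8 did not pass (11 and 1 over the list alone, median 0.67, camera adjusted p = 0.00905, or 0.111 with an estimated correlation).

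The lists of unfolded protein response and cholesterol genes were lower at D7. Of the unfolded protein response genes 1 of 23 rose, 11 fell and 11 did not pass (2 and 11 over the list alone, median -0.67, camera adjusted p = 5.84e-05). Among them were SEC24D (-2.19 ± 0.41), HYOU1 (-1.66 ± 0.30) and PDIA4 (-1.55 ± 0.18). Of the cholesterol genes 1 of 24 rose, 12 fell and 11 did not pass (1 and 14 over the list alone, median -0.64, camera adjusted p = 0.000332). Among them were STARD4 (-2.35 ± 0.48) and CYP51A1 (-2.04 ± 0.39). The DNA repair list stayed low, as 2 of 31 rose, 17 fell and 12 did not pass (2 and 18 over the list alone, median -0.85, camera adjusted p = 0.000234, or 0.17 with an estimated correlation). Among them were BARD1 (-2.08 ± 0.37) and FANCD2 (-1.56 ± 0.25). The cytidine deaminase CDA (2.24 ± 0.34), which inactivates cytidine analogues, rose while SHMT2 (-1.25 ± 0.26) and CAD (-1.10 ± 0.33) fell. The day changed 5398 genes (2907 higher, 2491 lower), or 3443 without library D7 A, and the share of higher genes went from 53.9 to 36.2 percent under total-sum scaling, which moved the median of all genes to -0.32.

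From D2 to D7 the acute genes receded. GDF15 (-1.99 ± 0.18, adjusted p = 6.33e-06), CDKN1A (-1.33 ± 0.23, adjusted p = 0.000996), PLK3 (-1.72 ± 0.25) and the death receptor TNFRSF10B (-1.72 ± 0.25) fell, and of the p53 targets 0 of 30 rose, 15 fell and 15 did not pass (1 and 17 over the list alone, median -0.62, camera adjusted p = 2.06e-07). In the NF-κB and secretory list 2 of 20 rose, 9 fell and 9 did not pass (3 and 10 over the list alone, median -0.64, camera adjusted p = 0.00378, or 0.104 with an estimated correlation). Among them were ICAM1 (-2.87 ± 0.30) and IL11 (-2.44 ± 0.42). The receptor NGFR (-4.29 ± 0.37) and the water channel AQP3 (-3.83 ± 0.20) fell as well. Rises included the Notch target HES1 (3.00 ± 0.19, adjusted p = 7.28e-08), NRG1 (3.57 ± 0.33), EIF5B (2.69 ± 0.68) and RPL22L1 (3.38 ± 0.37), which had fallen by D1. Of the ribosome biogenesis genes 11 of 40 rose, 0 fell and 29 did not pass (13 and 0 over the list alone, median 0.35, camera adjusted p = 8.42e-05), with NOP58 (2.10 ± 0.64) and NOP56 (1.55 ± 0.23), and the replication enzyme DUT (1.70 ± 0.22), TYMS (0.80 ± 0.19, adjusted p = 0.00675) and CCNB1 (0.96 ± 0.15) regained ground. YAP targets fell, as 0 of 17 rose, 9 fell and 8 did not pass (0 and 10 over the list alone, median -0.88, camera adjusted p = 4.45e-05, or 0.261 with an estimated correlation). The step changed 3377 genes (1506 higher, 1871 lower). It changed 5120 with the replicate letter as a block, 1073 in a fit of only these days and 287 without letter C.

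At D14 interferon-stimulated genes and the NF-κB and secretory genes were high in the cytoplasm. IFI27 (5.11 ± 0.42, adjusted p = 3.91e-07) and IFI6 (4.16 ± 0.31) rose, as did the siderophore binder LCN2 (5.35 ± 0.27, adjusted p = 8.72e-10), PRR15L (6.02 ± 0.55), KRTAP3-1 (7.42 ± 0.44) and the chemokine CXCL1 (3.12 ± 0.41). IFI27 (chromosome 14, 94104836 to 94116698), a mitochondrial protein of the interferon response, went from 21.6 ± 6.36 to 783 ± 231. Of the interferon-stimulated genes 15 of 26 rose, 0 fell and 11 did not pass (21 and 0 over the list alone, median 1.72, camera adjusted p = 5.24e-17). Among them were IFIT2 (4.21 ± 0.60) and IFIT3 (3.53 ± 0.45). Of the NF-κB and secretory genes 11 of 20 rose, 0 fell and 9 did not pass (15 and 0 over the list alone, median 0.89, camera adjusted p = 2.01e-08). Among them was IGFBP3 (2.96 ± 0.37). The matrix gene CCN2 (3.10 ± 0.52, adjusted p = 0.000777), a target of YAP, rose among targets of which 4 of 17 rose, 0 fell and 13 did not pass (4 and 0 over the list alone, median 0.49, camera adjusted p = 0.000253, or 0.309 with an estimated correlation).

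The falls at D14 were smaller. VIM (-2.14 ± 0.34, adjusted p = 0.000498), the intermediate filament of mesenchymal cells, AIFM1 (-1.77 ± 0.16), GCLM (-1.63 ± 0.27), which makes glutathione, and PCK2 (-1.84 ± 0.32) fell. Of the mitotic genes 0 of 35 rose, 15 fell and 20 did not pass (0 and 18 over the list alone, median -0.69, camera adjusted p = 7.1e-11). Among them was CDC20 (-1.46 ± 0.19). Of the DNA replication genes 0 of 35 rose, 21 fell and 14 did not pass (0 and 26 over the list alone, median -0.83, camera adjusted p = 3.14e-16). Among them were FEN1 (-1.43 ± 0.16) and MCM5 (-1.41 ± 0.21). CDKN1A (1.92 ± 0.23, adjusted p = 2.7e-05) stayed above D0, and of the p53 targets 10 of 30 rose, 0 fell and 20 did not pass (12 and 0 over the list alone, median 0.49, camera adjusted p = 3.93e-08). MDM2 (0.67 ± 0.31, adjusted p = 0.174) did not pass. Within the fluoropyrimidine list 0 of 27 rose, 9 fell and 18 did not pass (1 and 11 over the list alone, median -0.36, camera adjusted p = 0.000178), including TYMS (-0.98 ± 0.19), RRM2 (-1.20 ± 0.16) and TK1 (-1.18 ± 0.19). Aminoacyl-tRNA synthetases were lower, as 0 of 20 rose, 6 fell and 14 did not pass (0 and 15 over the list alone, median -0.73, camera adjusted p = 2.87e-08). Among them was WARS1 (-1.16 ± 0.18). The day changed 2035 genes, 1232 higher and 803 lower (60.5 percent higher, or 77.5 percent under total-sum scaling). With length and GC trends removed, a correction chosen after the data were seen, the share was 39.5 percent. In library D14 B the deviation followed GC content, as given above.

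Between D7 and D14 sterol genes rose and p53 targets fell. CCN2 (3.98 ± 0.52, adjusted p = 0.00022) rose most, with AXL (2.07 ± 0.42) and AMOTL2 (1.88 ± 0.48). Of the YAP targets 11 of 17 rose, 0 fell and 6 did not pass (14 and 0 over the list alone, median 1.16, camera adjusted p = 5.3e-06, or 0.366 with an estimated correlation). Sterol genes recovered, CYP51A1 (2.45 ± 0.39) among them, as 14 of 24 rose, 3 fell and 7 did not pass (14 and 3 over the list alone, median 1.24, camera adjusted p = 6.93e-05). Epithelial cadherin, CDH1 (2.09 ± 0.27), and mitotic genes such as PRC1 (2.74 ± 0.65) and ASPM (2.20 ± 0.50) rose. Of all mitotic genes 11 of 35 rose, 2 fell and 22 did not pass (11 and 2 over the list alone, median 0.57, camera adjusted p = 0.00855, or 0.394 with an estimated correlation). The p53 response ebbed further, with TP53I3 (-2.74 ± 0.20, adjusted p = 1.6e-06), RPS27L (-2.17 ± 0.39), FAS (-1.58 ± 0.43) and CDKN1A (-1.26 ± 0.23). Of all p53 targets 1 of 30 rose, 16 fell and 13 did not pass (1 and 16 over the list alone, median -0.80, camera adjusted p = 1.64e-05). Ribosomal protein mRNAs went back down, as 0 of 77 rose, 65 fell and 12 did not pass (0 and 73 over the list alone, median -1.13, camera adjusted p = 7.77e-15, or 0.47 with an estimated correlation). At D7 these genes held 22.7 percent of the reads in the divergent library A, against 14.72 in B and 15.93 in C. OXPHOS subunits went down too, as 0 of 51 rose, 42 fell and 9 did not pass (0 and 44 over the list alone, median -1.29, camera adjusted p = 4.17e-14, or 0.366 with an estimated correlation). Among them was NDUFB8 (-2.33 ± 0.53). The step changed 5656 genes, 46.4 percent of them higher, or 76.2 percent under total-sum scaling, which moved the median of all genes to 0.48.

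At D16 interferon-stimulated genes were among the largest rises. IFI27 (6.43 ± 0.42, adjusted p = 2.8e-08), IFI6 (5.32 ± 0.31, adjusted p = 7.97e-09) and IFITM1 (5.15 ± 0.41), a membrane protein that restricts virus entry, rose, and of the interferon-stimulated genes 25 of 26 rose, 0 fell and 1 did not pass (26 and 0 over the list alone, median 2.41, camera adjusted p = 5.38e-25). IFI27 reached 1960 ± 548. Of the antigen presentation genes 7 of 14 rose, 0 fell and 7 did not pass (10 and 0 over the list alone, median 0.95, camera adjusted p = 3.99e-07). Among them were PSMB9 (1.78 ± 0.30), HLA-F (1.64 ± 0.23) and HLA-B (1.06 ± 0.18). Of the epithelial junction genes 7 of 20 rose, 0 fell and 13 did not pass (9 and 0 over the list alone, median 0.48, camera adjusted p = 0.000131). Among them was the claudin CLDN4 (2.03 ± 0.27). Hypoxia and glucose genes were also higher, as ALDOC (2.50 ± 0.27), NDRG1 (2.36 ± 0.36), SLC2A3 (2.19 ± 0.28) and PDK1 (1.66 ± 0.28) rose within a list of which 9 of 27 rose, 2 fell and 16 did not pass (10 and 5 over the list alone, median 0.23, camera adjusted p = 0.024, or 0.545 with an estimated correlation). That list call was lost in 5 of 9 settings.

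Replication genes were low at D16, as 0 of 35 rose, 25 fell and 10 did not pass (0 and 31 over the list alone, median -0.99, camera adjusted p = 6.74e-20). Among them were POLA2 (-1.83 ± 0.38) and FEN1 (-1.78 ± 0.16, adjusted p = 1.28e-06). Of the mitotic genes 0 of 35 rose, 15 fell and 20 did not pass (0 and 19 over the list alone, median -0.73, camera adjusted p = 5.09e-10). The F-box gene SKP2 (-1.71 ± 0.24), which degrades cell cycle inhibitors, fell, and so did TYMS (-1.23 ± 0.19, adjusted p = 0.000256), RRM2 (-1.37 ± 0.16) and TK1 (-1.21 ± 0.19), as 1 of 27 rose, 11 fell and 15 did not pass (2 and 15 over the list alone, median -0.60, camera adjusted p = 4.35e-05). CDKN1A (1.33 ± 0.23, adjusted p = 0.000788) and BTG2 (2.17 ± 0.32) were still raised among the p53 targets, of which 8 of 30 rose, 0 fell and 22 did not pass (10 and 1 over the list alone, median 0.31, camera adjusted p = 0.000222). NF-κB and secretory genes were still high, as 12 of 20 rose, 0 fell and 8 did not pass (16 and 0 over the list alone, median 1.03, camera adjusted p = 2.74e-08). OXPHOS subunits were lower, as 0 of 51 rose, 13 fell and 38 did not pass (0 and 17 over the list alone, median -0.59, camera adjusted p = 1.95e-08, or 0.379 with an estimated correlation). The day changed 2659 genes, of which 56.6 percent were higher, or 72.8 percent under total-sum scaling. With length and GC trends removed the share was 37.7 percent at D16, and 47.3, 44.5 and 46.3 percent at D1, D2 and D7, so the balance of directions depends on the correction.

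Between D14 and D16 no single gene passed in the cytoplasm in the fit of all days, with or without the replicate block. Of 15889 genes, 230 had an unadjusted p under 0.05 and 0 an adjusted one by limma, against 3 by DESeq2 and 0 by edgeR on the recovered reads. CDKN1A (-0.59 ± 0.23, adjusted p = 1) and GDF15 (-0.24 ± 0.18, adjusted p = 1) did not pass. A fit of only these days also called 0 genes. With the replicate block in that fit, a choice made after the data were seen, 1176 genes passed (662 higher, 514 lower), CDKN1A and GDF15 among them. The result thus depended on both choices together, and the 0 calls do not show that the days were alike. As groups, interferon-stimulated genes were higher, as 0 of 26 rose, 0 fell and 26 did not pass (10 and 0 over the list alone, median 0.73, camera adjusted p = 2.23e-30). Glycolysis and hypoxia genes were higher as well, as 0 of 27 rose, 0 fell and 27 did not pass (6 and 0 over the list alone, median 0.47, camera adjusted p = 9.88e-26). The p53 targets were lower, as 0 of 30 rose, 0 fell and 30 did not pass (0 and 0 over the list alone, median -0.20, camera adjusted p = 3.12e-06). Histones were also lower, as 0 of 11 rose, 0 fell and 11 did not pass (0 and 0 over the list alone, median -0.60, camera adjusted p = 8.69e-12). These 4 camera calls held with an estimated correlation (adjusted p = 5.68e-07, 0.02, 0.0101 and 0.0384).

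**Figure D2:**
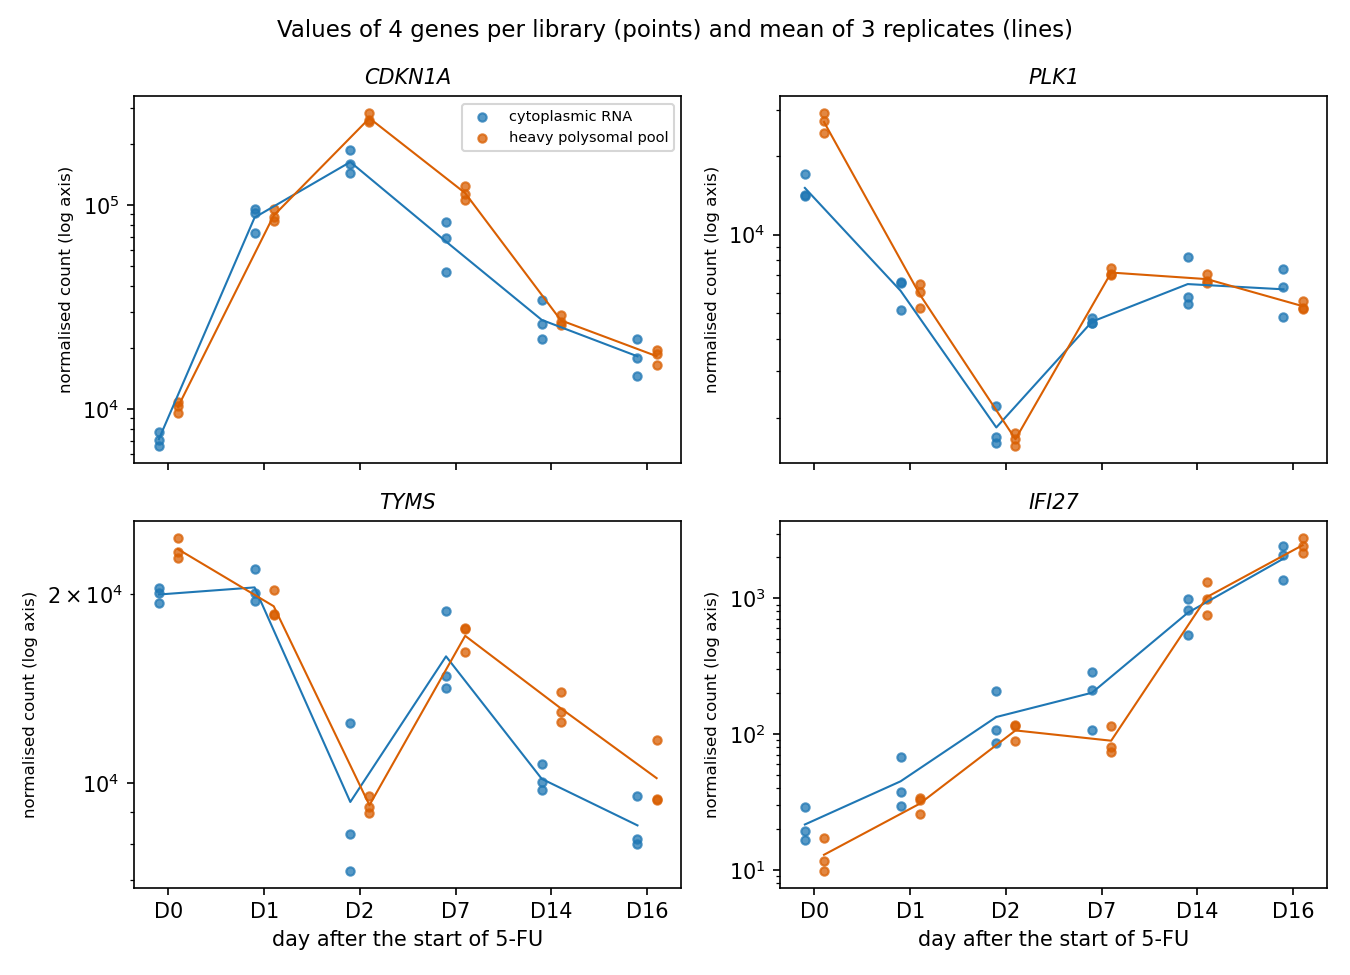
Deposited normalised counts (log axis) of CDKN1A, PLK1, TYMS and IFI27 in each library by day (days spaced evenly), in cytoplasmic RNA and the heavy polysomal pool, with points for libraries and lines for the mean of 3 replicates. CDKN1A is highest and PLK1 lowest at D2 in both fractions, and IFI27 is highest at D16.

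In the heavy pool at D1, p53 targets were higher, as in the cytoplasm. CDKN1A (3.11 ± 0.09, adjusted p = 8.96e-17), GDF15 (3.29 ± 0.16, adjusted p = 2.3e-13), MDM2 (2.74 ± 0.11, adjusted p = 8.33e-15) and FAS (3.04 ± 0.14) rose, and of the p53 targets 30 of 30 rose, 0 fell and 0 did not pass (30 and 0 over the list alone, median 1.77, camera adjusted p = 9.39e-33). NECTIN4 (5.45 ± 0.21), PTAFR (4.80 ± 0.16), the laminin LAMA3 (4.13 ± 0.13) and the zinc finger factor SNAI2 (4.10 ± 0.25) were among the largest rises. Of the apoptosis regulators 17 of 26 rose, 2 fell and 7 did not pass (17 and 2 over the list alone, median 0.51, camera adjusted p = 1.33e-06). Among them was PMAIP1 (2.00 ± 0.11). The kinase PLK1 (-2.19 ± 0.09, adjusted p = 1.08e-14) and CDC20 (-1.60 ± 0.09) fell, as did the amino acid response genes CHAC1 (-1.96 ± 0.19), SLC6A9 (-1.90 ± 0.15) and ATF4 (-1.28 ± 0.09, adjusted p = 1.17e-10), the transcription factor of that response. Of all ATF4 targets 4 of 26 rose, 19 fell and 3 did not pass (4 and 19 over the list alone, median -0.69, camera adjusted p = 9.95e-06, or 0.223 with an estimated correlation). Ribosomal protein mRNAs thinned out, as 0 of 77 rose, 47 fell and 30 did not pass (0 and 48 over the list alone, median -0.31, camera adjusted p = 4.34e-08, or 0.451 with an estimated correlation). Among them were RPL10A (-1.56 ± 0.09) and RPL3 (-1.16 ± 0.09). Of 15852 genes 7447 changed, 42.7 percent of them higher, or 67.9 percent under total-sum scaling.

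At D2 cell cycle mRNAs fell in the pool. PLK1 (-4.02 ± 0.09, adjusted p = 1.59e-19), CDC20 (-3.44 ± 0.09), CCNB1 (-3.44 ± 0.10) and MCM2 (-3.33 ± 0.14, adjusted p = 4.67e-15) fell, and CDKN1A (4.70 ± 0.09, adjusted p = 2.13e-20) rose from 10200 ± 602 to 266000 ± 13700. Of the mitotic genes 0 of 35 rose, 34 fell and 1 did not pass (0 and 35 over the list alone, median -1.87, camera adjusted p = 7.5e-16, or 0.176 with an estimated correlation). Of the DNA replication genes 0 of 35 rose, 34 fell and 1 did not pass (0 and 34 over the list alone, median -1.74, camera adjusted p = 4.82e-16, or 0.184 with an estimated correlation). Of the p53 targets 29 of 30 rose, 1 fell and 0 did not pass (29 and 1 over the list alone, median 2.05, camera adjusted p = 1.37e-17). The serine enzyme PHGDH (-3.43 ± 0.16), ATF4 (-2.23 ± 0.09) and the asparagine synthetase ASNS (-2.26 ± 0.22) fell, as did all aminoacyl-tRNA synthetases, where 0 of 20 rose, 20 fell and 0 did not pass (0 and 20 over the list alone, median -1.31, camera adjusted p = 3.6e-10, or 0.226 with an estimated correlation). Of the ribosome biogenesis genes 1 of 40 rose, 35 fell and 4 did not pass (1 and 35 over the list alone, median -1.09, camera adjusted p = 7.98e-10, or 0.243 with an estimated correlation). Among them was NAT10 (-2.58 ± 0.16). Of the TOP translation factors, which share the mTOR-dependent start of ribosomal protein mRNAs, 1 of 19 rose, 16 fell and 2 did not pass (1 and 16 over the list alone, median -0.60, camera adjusted p = 0.000459, or 0.268 with an estimated correlation). Among them were HNRNPA1 (-1.97 ± 0.10), NPM1 (-1.72 ± 0.10) and EEF1A1 (-1.03 ± 0.10). TYMS (-1.35 ± 0.09, adjusted p = 6.97e-12) fell. Changes numbered 10290, 46.8 percent higher, or 71.7 percent under total-sum scaling.

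At D7 every mitochondrially encoded mRNA was low in the heavy pool. MT-ND2 (-4.25 ± 0.28, adjusted p = 2.68e-11), MT-ND4L (-4.05 ± 0.26), MT-ATP8 (-4.02 ± 0.26) and MT-CO1 (-2.89 ± 0.26, adjusted p = 3.73e-09) fell, as 0 of 13 rose, 13 fell and 0 did not pass (0 and 13 over the list alone, median -3.28, camera adjusted p = 4.34e-08, or 0.268 with an estimated correlation). The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2, which were not on the list, changed by -3.30 ± 0.30 and -2.61 ± 0.29. KRTAP3-1 (9.01 ± 0.25), KLK5 (5.20 ± 0.19) and NRG1 (5.17 ± 0.17) were among the largest rises. The chaperones HSP90B1 (-1.86 ± 0.13) and HSPA5 (-1.71 ± 0.17) fell, and of the unfolded protein response genes 3 of 23 rose, 19 fell and 1 did not pass (3 and 19 over the list alone, median -0.91, camera adjusted p = 2.94e-05, or 0.249 with an estimated correlation). The p53 targets stayed up, as 28 of 30 rose, 0 fell and 2 did not pass (28 and 0 over the list alone, median 1.41, camera adjusted p = 4.82e-16). Of the mitotic genes 0 of 35 rose, 32 fell and 3 did not pass (0 and 34 over the list alone, median -1.56, camera adjusted p = 6.77e-13, or 0.184 with an estimated correlation). Of the DNA replication genes 1 of 35 rose, 34 fell and 0 did not pass (1 and 34 over the list alone, median -1.21, camera adjusted p = 2.66e-12, or 0.223 with an estimated correlation). Among them was POLE (-2.09 ± 0.14). The day changed 10066 genes around a median of -0.11 for all genes, 42.5 percent of them higher, or 64.5 percent under total-sum scaling.

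At D14 ribosomal protein mRNAs were high in the heavy pool. RPL12 (1.99 ± 0.10, adjusted p = 1.45e-13), RPS12 (1.73 ± 0.10), RPS20 (1.64 ± 0.09) and RPL17 (1.63 ± 0.10) rose, as 69 of 77 rose, 0 fell and 8 did not pass (69 and 0 over the list alone, median 0.84, camera adjusted p = 6.58e-16, or 0.249 with an estimated correlation), while the kinase MTOR (-2.09 ± 0.12), which drives their translation, and the scaffold EIF4G1 (-2.03 ± 0.12) fell. MT-ATP8 (-5.00 ± 0.26, adjusted p = 4.18e-13) was the deepest fall of the mitochondrial mRNAs, of which 0 of 13 rose, 13 fell and 0 did not pass (0 and 13 over the list alone, median -3.39, camera adjusted p = 3.66e-07, or 0.301 with an estimated correlation). IFI27 (6.20 ± 0.22, adjusted p = 1.74e-15), LCN2 (6.01 ± 0.16) and CXCL1 (4.67 ± 0.36) rose, and of the interferon-stimulated genes 21 of 26 rose, 2 fell and 3 did not pass (21 and 2 over the list alone, median 1.56, camera adjusted p = 3.66e-07, or 0.245 with an estimated correlation). The p53 targets split in the pool, as 17 of 30 rose, 9 fell and 4 did not pass (17 and 9 over the list alone, median 0.65, camera adjusted p = 0.0287, or 0.36 with an estimated correlation). Of the aminoacyl-tRNA synthetases 0 of 20 rose, 20 fell and 0 did not pass (0 and 20 over the list alone, median -1.38, camera adjusted p = 1.46e-08, or 0.249 with an estimated correlation). Of the DNA repair genes 2 of 31 rose, 26 fell and 3 did not pass (3 and 26 over the list alone, median -0.91, camera adjusted p = 2.53e-05, or 0.226 with an estimated correlation). Changes reached 11413 genes, 47.8 percent higher, or 65 percent under total-sum scaling.

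At D16 replication mRNAs were scarce in the heavy pool. MCM5 (-3.07 ± 0.13, adjusted p = 7.5e-15), MCM7 (-2.76 ± 0.12) and FEN1 (-2.72 ± 0.12) fell, as 0 of 35 rose, 35 fell and 0 did not pass (0 and 35 over the list alone, median -1.83, camera adjusted p = 4.82e-16, or 0.184 with an estimated correlation), together with the Integrator subunit INTS1 (-2.87 ± 0.13) and EDC4 (-2.90 ± 0.18). IFI27 (7.50 ± 0.22, adjusted p = 4.61e-17) rose from 12.9 ± 3.84 to 2460 ± 303. Of the interferon-stimulated genes 24 of 26 rose, 0 fell and 2 did not pass (24 and 1 over the list alone, median 2.24, camera adjusted p = 3.97e-10, or 0.223 with an estimated correlation). Ribosomal protein mRNAs stayed above D0, as 58 of 77 rose, 1 fell and 18 did not pass (58 and 1 over the list alone, median 0.59, camera adjusted p = 3.03e-09, or 0.391 with an estimated correlation). Of the RNAs listed as nuclear-retained 9 of 9 rose, 0 fell and 0 did not pass (9 and 0 over the list alone, median 1.50, camera adjusted p = 0.000912, or 0.249 with an estimated correlation). Among them were SNHG12 (2.97 ± 0.16) and NEAT1 (1.63 ± 0.22). The list was set from general knowledge, and the site of these RNAs in the cells was not measured. CDKN1A (0.82 ± 0.09, adjusted p = 3.88e-08) was only slightly raised, and of the p53 targets 15 of 30 rose, 11 fell and 4 did not pass (15 and 11 over the list alone, median 0.27, camera adjusted p = 0.28). The ribosome biogenesis genes were low, as 1 of 40 rose, 37 fell and 2 did not pass (1 and 37 over the list alone, median -1.10, camera adjusted p = 4.77e-10, or 0.237 with an estimated correlation). Among them were PES1 (-2.15 ± 0.09) and BOP1 (-2.14 ± 0.10). The day changed 11548 genes, 49.7 percent higher, or 70.7 percent under total-sum scaling.

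The changes of the cytoplasm and of the heavy pool against D0 correlated across genes with r = 0.49 ± 0.07 at D1, 0.72 ± 0.08 at D2, 0.64 ± 0.09 at D7, 0.43 ± 0.15 at D14 and 0.49 ± 0.14 at D16 (mean ± SD over the 3 letters). Genes are not independent replicates, so no p-value is attached.

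Polysome association is the change of the heavy pool beyond that of the cytoplasm, tested as an interaction. Values are as fitted, and the median of all genes lay between -0.10 and -0.09. At D1 TUBA1B (-1.65 ± 0.22, adjusted p = 0.000115), an alpha tubulin, and GAPDH (-1.47 ± 0.26, adjusted p = 0.00464), a glycolytic enzyme, lost association, as did HMCN2 (-2.22 ± 0.44), and VPS13C (1.74 ± 0.33) gained it. Of the ribosomal protein mRNAs 0 of 77 rose, 9 fell and 68 did not pass (0 and 27 over the list alone, median -0.82, camera adjusted p = 7.15e-13, or 0.722 with an estimated correlation). CDKN1A (-0.49 ± 0.24, adjusted p = 0.186) and MDM2 (1.15 ± 0.34, adjusted p = 0.0512) did not pass. MDM2 passed with the replicate block in the fit of all libraries, but not with 1 ratio per culture and the block. Calls numbered 661 (125 higher, 536 lower), 1108 with the replicate block and 44 under total-sum scaling, so single genes here are uncertain.

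At D2 mitochondrial mRNAs fell in the heavy pool relative to the cytoplasm. MT-ATP8 (-3.47 ± 0.51, adjusted p = 0.000243), MT-ND3 (-3.38 ± 0.67) and MT-CO2 (-3.01 ± 0.61) fell, as 0 of 13 rose, 10 fell and 3 did not pass (0 and 11 over the list alone, median -2.53, camera adjusted p = 6.06e-15, or 0.249 with an estimated correlation). For MT-CO2 the larger part was a cytoplasmic rise (1.96, against -1.05 in the heavy pool). Among nuclear genes CCNB1 (-1.32 ± 0.16, adjusted p = 3.3e-05), CDC20 (-1.46 ± 0.21), ATF4 (-1.24 ± 0.26, adjusted p = 0.008) and MCM7 (-1.15 ± 0.24) lost association, and of the DNA replication genes 0 of 35 rose, 9 fell and 26 did not pass (0 and 18 over the list alone, median -0.58, camera adjusted p = 2.56e-11, or 0.249 with an estimated correlation). Of 328 calls 1.8 percent were higher, a share that turned to 77.3 percent of 132 calls under total-sum scaling, which moved the median of all genes to 0.39, so these directions hold only relative to the other genes.

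At D7 mitochondrial mRNAs again lost association, and ribosomal protein mRNAs lagged behind their cytoplasmic rise. MT-ND3 (-5.06 ± 0.67, adjusted p = 8.35e-05) and MT-ND2 (-4.43 ± 0.55) fell, as 0 of 13 rose, 11 fell and 2 did not pass (0 and 13 over the list alone, median -2.98, camera adjusted p = 1.54e-21, or 0.249 with an estimated correlation). Of the ribosomal protein mRNAs 0 of 77 rose, 23 fell and 54 did not pass (0 and 73 over the list alone, median -1.12, camera adjusted p = 1.01e-25, or 0.574 with an estimated correlation). Among them were RPS27 (-1.74 ± 0.41) and RPLP1 (-1.69 ± 0.38). The median ratio of the list went from -1.29 at D0 to -3.05 at D7 in letter A, from -0.98 to -1.53 in B and from -0.84 to -1.78 in C. Of the TOP translation factors 0 of 19 rose, 4 fell and 15 did not pass (0 and 11 over the list alone, median -0.76, camera adjusted p = 3.46e-06, or 0.249 with an estimated correlation). UBE2V1 (2.53 ± 0.49, adjusted p = 0.00293) and the sterol demethylase CYP51A1 (1.82 ± 0.42) rose. Calls numbered 627, 964 with the replicate block and 248 without cytoplasmic library D7 A, and 19 percent were higher, against 88.3 percent of 1589 under total-sum scaling.

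**Figure D3:**
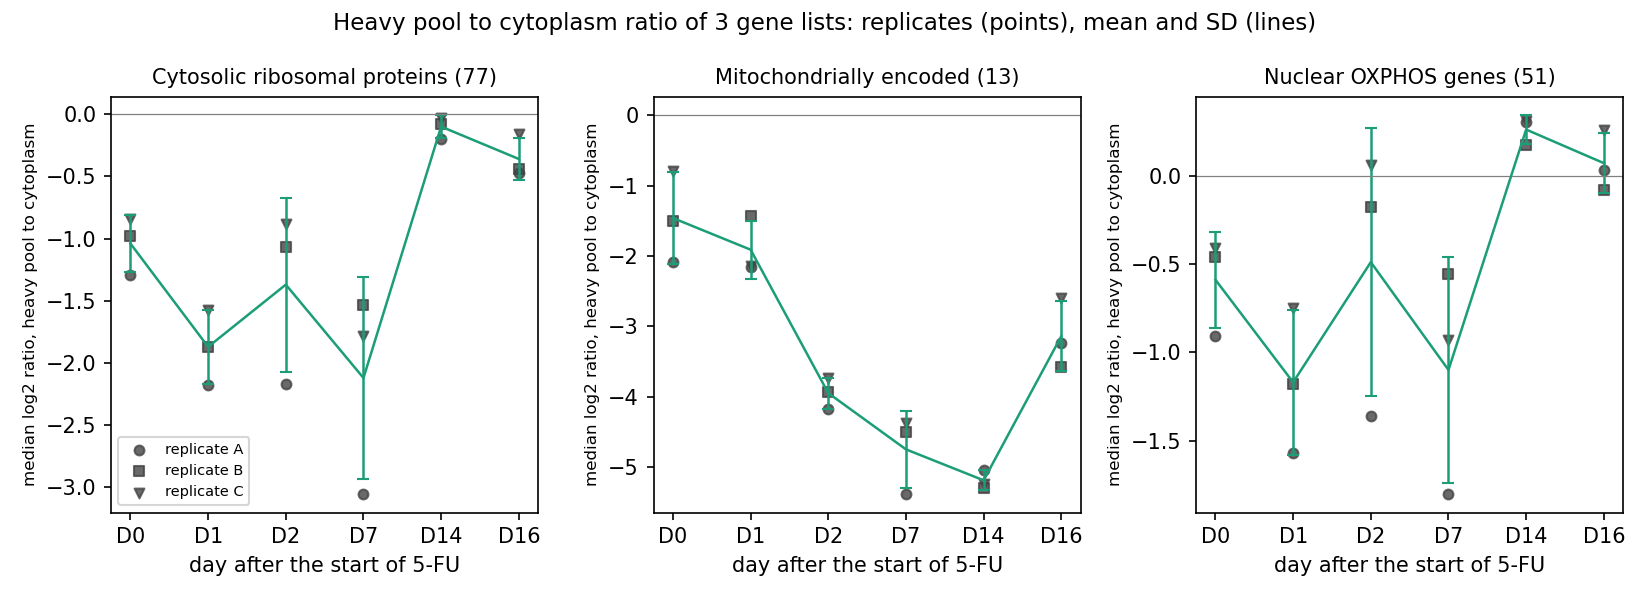
Median log2 ratio of the heavy pool to the cytoplasm for 3 gene lists by day (days spaced evenly), with points for the 3 replicate letters and lines for their mean and SD. For ribosomal protein mRNAs the mean ratio runs from -1.04 at D0 to -2.12 at D7 (-3.05 in letter A) and -0.10 at D14, and for mitochondrially encoded mRNAs from -1.46 at D0 to -5.19 at D14.

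At D14 polysome association changed widely. RPL17 (1.98 ± 0.21, adjusted p = 4.94e-07), RPL12 (2.22 ± 0.41, adjusted p = 0.000481), RPS20 (1.91 ± 0.44) and the mTOR activator RHEB (1.81 ± 0.28) rose, and of the ribosomal protein mRNAs 27 of 77 rose, 0 fell and 50 did not pass (32 and 0 over the list alone, median 0.83, camera adjusted p = 1.39e-12, or 0.722 with an estimated correlation). Their median ratio of heavy pool to cytoplasm was -0.10 ± 0.09 at D14 against -1.04 ± 0.23 at D0 (mean ± SD, n = 3). Nuclear OXPHOS subunits gained with them, as 21 of 51 rose, 7 fell and 23 did not pass (25 and 8 over the list alone, median 0.87, camera adjusted p = 0.000403, or 0.722 with an estimated correlation), with NDUFV2 (2.06 ± 0.46) and UQCRQ (1.76 ± 0.41), and so did IER3IP1 (2.72 ± 0.52), POLR2J (2.52 ± 0.34), PPDPF (2.49 ± 0.32) and the translation repressor EIF4EBP1 (1.53 ± 0.26). The kinases MTOR (-1.59 ± 0.34) and EEF2K (-1.39 ± 0.39) lost association. MT-ND4L (-5.52 ± 0.52, adjusted p = 8.67e-08) and MT-ATP8 (-5.18 ± 0.51) fell, as 0 of 13 rose, 12 fell and 1 did not pass (0 and 13 over the list alone, median -4.01, camera adjusted p = 1.47e-14, or 0.249 with an estimated correlation). Of the DNA replication genes 2 of 35 rose, 20 fell and 13 did not pass (2 and 22 over the list alone, median -0.72, camera adjusted p = 1.29e-05, or 0.574 with an estimated correlation). CDKN1A (-0.51 ± 0.24, adjusted p = 0.112) did not pass. Of 4490 calls 40.8 percent were higher, or 78.6 percent under total-sum scaling.

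At D16 the pattern of D14 was present in the same comparison with D0. FLNA (-2.46 ± 0.43, adjusted p = 0.000189), an actin crosslinker, MCM7 (-1.71 ± 0.24, adjusted p = 2.94e-05), NOP2 (-2.41 ± 0.66) and CCNB1 (-1.11 ± 0.16) lost association, and DTD2 (2.54 ± 0.33, adjusted p = 1.15e-05), SNX10 (2.90 ± 0.69) and RPL12 (1.89 ± 0.41) gained it. Of the DNA replication genes 2 of 35 rose, 23 fell and 10 did not pass (2 and 25 over the list alone, median -0.95, camera adjusted p = 2.66e-08, or 0.249 with an estimated correlation). Of the aminoacyl-tRNA synthetases 0 of 20 rose, 14 fell and 6 did not pass (0 and 14 over the list alone, median -0.94, camera adjusted p = 7e-07, or 0.249 with an estimated correlation), of the ribosomal protein mRNAs 12 of 77 rose, 0 fell and 65 did not pass (4 and 0 over the list alone, median 0.65, camera adjusted p = 2.59e-07, or 0.722 with an estimated correlation). Of the mitochondrial mRNAs 0 of 13 rose, 7 fell and 6 did not pass (0 and 10 over the list alone, median -1.44, camera adjusted p = 0.00146, or 0.722 with an estimated correlation). The oncogene MYC (-1.22 ± 0.36, adjusted p = 0.0113) fell. Of 4687 calls 39.2 percent were higher, or 74.7 percent under total-sum scaling. Since all comparisons with D0 share its libraries, D14 and D16 are not separate evidence.

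Of 589 camera tests over all lists and comparisons, 261 passed with the preset correlation and 56 with an estimated one. In the cytoplasm against D0 the calls that held included those of p53 targets, aminoacyl-tRNA synthetases and interferon-stimulated genes on all days, of mitosis and DNA replication genes from D2 on, of ribosome biogenesis on D1, D2, D14 and D16, and of apoptosis regulators on D1, D2 and D7. Those of NF-κB and secretory genes held on D1, D2, D14 and D16, of the unfolded protein response from D2 on, and of fluoropyrimidine metabolism on D14 and D16. Cholesterol genes held at D7, antigen presentation and epithelial junction genes at D16, and the 3 markers of other lineages at D1. Between days the p53 targets held in every step, ribosome biogenesis from D2 to D7 and cholesterol genes from D7 to D14. In the heavy pool the p53 targets at D1, D2 and D7 and the apoptosis regulators at D1 held, and no list call on polysome association did.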

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

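The tests of mitochondrial ribosomal RNA and of the cytoplasmic level, the comparison of ribosomal protein mRNAs with the mean of D1, D2 and D7, and all tests of libraries D14 B and D16 B were chosen only after the result was seen.

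The first pattern is the fall of mitochondrially encoded mRNAs in the heavy pool at D7 and D14. The mitochondrial ribosomal RNAs, which cytosolic ribosomes do not translate, fell with them at D7, the smaller of the 2 changes being -2.61, so less mitochondrial material in the heavy pool is a candidate explanation. A lower level in the cytoplasmic extract was not seen (list median -0.04), and removing the trend with exon length and GC content left a median of -3.59 with 13 of 13 genes called. Whether mitochondria changed in the cells or only in their sedimentation stays open. Because the labels say that mitochondria were pelleted before the gradient, these values do not measure mitochondrial translation.

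The second pattern is the rise of ribosomal protein mRNAs in the heavy pool relative to the cytoplasm at D14. Removing the trend with exon length and GC content left the list median 0.89 above all genes (30 of 77 called). The trend as measured thus did not account for the rise. The values argue against the D0 libraries (1.61 above the mean of D1, D2 and D7). The 1458 other genes matched on exon length lay 0.13 above all genes, against 0.93 for the list. In the trend and in this match, exon length sums all annotated exons of a gene and can exceed its mRNA. Neither a trend with mRNA length nor a shift of short mRNAs was thus excluded. Scaling was not tested, since the difference from all genes under total-sum scaling (0.93, 70 of 77 called) cancels a shift of whole libraries. Nuclear OXPHOS mRNAs shared the rise (mean ratio -0.59 at D0, 0.26 at D14). A change in translation is possible, and an mTOR inhibitor at D14 might test it. The cause stays open. The list's camera call did not hold with an estimated correlation (adjusted p = 0.722).

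The third pattern is that cytoplasmic libraries D14 B and D16 B lay apart from their groups, with deviations that correlated with each other (r = 0.94). Their deviation followed GC content (the smaller r was 0.76), as a technical difference of these libraries could give. Such a trend was not confined to them. In the cytoplasm r with GC content was -0.57 for D0 B, 0.59 for D1 B and -0.56 for D2 C, though 0.01 for D7 A. Exon length did not account for it (larger r -0.11), and neither did a state of the culture that also reached the heavy pool (larger r 0.23). The step at which the deviation of D14 B and D16 B arose stays open.

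Genes that moved in opposite directions in the fractions, each called in both and in their difference, were picked out as differing between groups. Higher in the cytoplasm and lower in the heavy pool were 37 genes at D1 (GAPDH among them), 14 at D2, 116 at D7, 14 at D14 and 28 at D16. The reverse held for 5 genes at D1, 1 at D2, 12 at D7 (UBE2V1 among them), 51 at D14 and 94 at D16. Of 2 settings applied here after the counts were seen, total-sum scaling gave 5, 7, 26, 3 and 1 genes by day for the first kind and 2, 8, 109, 65 and 130 for the second. The replicate block gave 102, 23, 170, 69 and 95 for the first and 28, 2, 30, 166 and 225 for the second, so these counts depend on the processing. Ribosomal protein genes were called up in the cytoplasm and down in the heavy pool at D1 (camera adjusted p of the difference 7.15e-13, or 0.722 with an estimated correlation), though 0 of 77 passed in the cytoplasm. Mitochondrially encoded genes were called likewise at D2 (6.06e-15, or 0.249 with an estimated correlation).

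The libraries of each pair of groups were also regrouped in all 10 possible splits, too few for a share under 0.05. Every split but the real one mixed libraries of both groups, which adds a real difference to the spread. Low counts in those splits were thus likely beforehand and do not measure a rate of false calls. The real grouping called most genes in 1 of 10 splits for 18 comparisons. In the cytoplasm it gave 2850, 3943, 5398, 2035 and 2659 calls against D0 by day and 5656 from D7 to D14, and the highest other split gave 0 each time. From D2 to D7 it gave 3377 and another split gave 1917, which points to structure among the samples (5120 with the replicate block). In the heavy pool it gave 7447, 10290, 10066, 11413 and 11548, the highest other being 1 at D7 and 0 on the other days. For polysome association it gave 661, 328, 627, 4490 and 4687, and 7280 at baseline, with 0 as the highest other. All 10 splits of D14 and D16 gave 0. For the F tests 1 of 100 regroupings, the real one, gave most calls. It gave 9769 against 102 in the cytoplasm, 15078 against 2967 in the heavy pool and 8602 against 4 for polysome association (shares under 0.05).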

How the results depend on the processing

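The fit without 3 divergent cytoplasmic libraries, the removal of length and GC trends, the correlations without each letter and the paired fit of D14 and D16 were chosen after seeing the data. No call of a named gene or list reversed under any setting. Most named genes were picked as called in these same data, many with the same sign in all letters, so reversals were unlikely beforehand. Among all genes the balance did turn, as association calls at D2 went from 1.8 to 77.3 percent higher under total-sum scaling. Of 295 named gene results 43 calls were lost without letter C, 20 without B, 12 without A and 8 under total-sum scaling. The heavy pool held best, and the counts for polysome association at D1, D2 and D7 held least. The cause was not tested, though fewer libraries lower the power of every leave-one-out fit. Every alternative written beforehand was run.

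With the replicate block, calls went to 5120 (2482 higher) for D7 against D2, 1108 (289 higher) for association at D1 and 964 (200 higher) at D7, and MDM2 in polysome association D1 vs D0 passed. In the fit of all days the block changed no other call of a named gene or list. In the fit of only D14 and D16 the block let CDKN1A and GDF15 pass. Total-sum scaling gave 44 (22 higher), 132 (102 higher) and 1589 (1403 higher) association calls at D1, D2 and D7. From 1 ratio per culture came 18, 125 and 274, or 412, 195 and 1066 with the block, where MDM2 did not pass at D1. DESeq2 gave 1417, 509 and 1398, and 3 genes for D16 against D14, and edgeR gave 403 at D1. For D16 against D14 the fit of only these groups gave 0, and 1176 (662 higher) with the block. A fit of only the groups compared gave 5494 for the cytoplasm at D1, 3242 for D14 against D7, 1073 for D7 against D2 and 3798 for association at D1. Without the 3 divergent libraries (D7 A, D14 B and D16 B) these were 5352 for the cytoplasm at D1, 3086 at D14, and 4073 and 1536 for association at D1 and D2.

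With length and GC trends removed, the cytoplasm gave 6080 at D2, 4535 at D14, 5147 at D16, 5459 for D7 against D2 and 2 for D16 against D14, and association 314 at D1 and 1324 at D7. With the block as well, the cytoplasm gave 4919, 6950, 5512 and 6025 at D1, D2, D14 and D16, 6624 for D7 against D2 and 2 for D16 against D14, and association 431, 593 and 1667 at D1, D2 and D7. Of the list tests 56 passed with an estimated correlation and 321 with fry. Spearman correlation was 0.38 at D1, and differences of group means, without pairing, gave r = 0.57, 0.84 and 0.73 at D1, D2 and D7.

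Each comparison was rerun without each letter and each library compared. By day this gave 531 to 2288, 1794 to 4046, 1322 to 5770, 253 to 1743 and 438 to 2131 cytoplasmic calls. D7 against D2 gave 287 to 5000, D14 against D7 1191 to 6028 and D16 against D14 0. The heavy pool gave 5270 to 7202, 8607 to 9822, 8292 to 9685, 9912 to 10885 and 10148 to 11304 by day. Association gave 0 to 1037, 4 to 1227, 25 to 2078, 1297 to 4422 and 1768 to 4893, and 4927 to 6756 at baseline. Without a letter only, F tests gave 3354 to 7414 (cytoplasm), 14204 to 14701 (heavy pool) and 4499 to 6239 (association) and list tests 256 to 271. Correlations then were 0.45 to 0.51, 0.67 to 0.74, 0.60 to 0.69, 0.37 to 0.51 and 0.45 to 0.57 by day.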

Other observations

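At D14 in the cytoplasm, replication-dependent histone mRNAs were high while DNA replication genes were low, as 7 of 11 rose, 0 fell and 4 did not pass (7 and 0 over the list alone, median 1.43, camera adjusted p = 8.58e-07, or 0.0807 with an estimated correlation). Among them was H2AC6 (2.55 ± 0.27). The aldo-keto reductase AKR1C3 (2.19 ± 0.35), which detoxifies carbonyls, rose and the quinone reductase NQO1 (-1.16 ± 0.17) fell. In the step from D7 to D14 LRIG1 (2.63 ± 0.43) and ZNRF3 (1.08 ± 0.26) of the Wnt and stem cell list rose, as 9 of 17 rose, 0 fell and 8 did not pass (9 and 0 over the list alone, median 0.72, camera adjusted p = 0.00249, or 0.366 with an estimated correlation). The genes TPP1 (1.75 ± 0.26) and NPC1 (1.58 ± 0.25), whose proteins act in the lysosome, rose too.

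Mitochondrial transcripts and the D14 rise of ribosomal protein mRNAs might share a cause in the make-up of the heavy pool, which was not tested. The log2 ratio of heavy pool to cytoplasm of mitochondrial mRNAs was -1.46 ± 0.65 at D0 and already -4.75 ± 0.55 at D7 (mean ± SD, n = 3). That of ribosomal protein mRNAs was -1.04 ± 0.23 at D0, -2.12 ± 0.81 at D7 and -0.10 ± 0.09 at D14. These time courses argue against a single cause that acted on both lists in the same way at D7 and D14. Polysome gradients with spike-in RNA at D7 and D14 could separate a change in the pool from a change in translation.

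Interferon-stimulated genes rose beside NF-κB genes, and neither released nucleic acid nor secreted interferon was measured here. For these genes the cytoplasmic list call at D16 held with the replicate block and with an estimated correlation. Between D14 and D16 the fit of all days called 0 genes with or without the replicate block, and 2 with the block and length and GC trends removed. DESeq2 called 3. A fit of only these days called 0, and 1176 with the block.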
